A study of Mus musculus with 9 samples.

How the data were processed

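Kidney cells from male mice aged 9 to 12 weeks and weighing 25 to 30 g were sorted for the red fluorescent protein tdTomato and profiled by sequencing of polyadenylated RNA. The 9 libraries fell into 3 groups of 3 biological replicates. In the uninjured group, a tamoxifen-inducible Cre recombinase placed behind Slc34a1, which encodes a phosphate transporter of the proximal tubule, had switched on tdTomato. In the other groups the Cre recombinase was placed behind Sox9, a transcription factor of progenitor and injured epithelia, and the mice had ischemia-reperfusion injury of both kidneys. For the 48 h group tamoxifen was given when the injury was induced and cells were collected 48 h later. For the d14 group tamoxifen was given on days 10 and 12 after injury and cells were collected on day 14. Cells came from minced cortex and outer medulla digested on ice, and up to 30 ng of RNA per sample went into a strand-specific library. The Cre allele, the injury and the schedule of tamoxifen differ together between the uninjured group and the Sox9 groups, and the schedule also differs between 48 h and d14, so no comparison separates them. Whether uninjured mice had a sham operation is not given in the sources used here.

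The table deposited by the authors holds RSEM expected counts per gene and library, already as whole numbers and not scaled to a common depth. The submitters' processing notes name bcl2fastq 2.20, STAR 2.6.1, RSEM 1.2.28, DESeq2 1.26.0 and R 3.6.3, with no role stated, and list a mouse and a human genome build. All gene identifiers are mouse, so the mouse build mm10 was taken. The release of the gene annotation and the strand setting of the counting are not given in the sources used here. RSEM divides reads that map to several genes among them, so values of near-identical copies (Sprr2f, the Cyp2d, Cyp4a12, Hba and Gsta genes, and ribosomal protein genes with pseudogenes) carry an uncertainty that the counts do not show. The table lists 55385 genes and 92 spike-in sequences, the latter all at 0 counts and not used. Of the gene identifiers, 54487 occur with the same version in GENCODE M21 and 55144 when versions are ignored. Coordinates are 1-based positions in GRCm38 (mm10) from that release.

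Total counts are given below. A gene with no count in a library allows up to 3 counts there, which is 0.0651 to 0.431 CPM (counts scaled by library size) depending on the library, 0.0263 CPM over the uninjured group and 0.0645 CPM over the 48 h group. These floors and the 95% Poisson intervals of ratios cover counting error only, since the reads carry no molecular identifiers.

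Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15519 genes holding at least 99.89% of the counts of every library. Libraries were scaled by TMM, and CPM values use the TMM-scaled library size. A quasi-likelihood model with a mean per group and robust dispersion was fitted to all 9 libraries, and each of the 3 comparisons was tested with the quasi-likelihood F-test. Adjusted p values are Benjamini-Hochberg within a comparison, and a gene is called higher or lower at adjusted p under 0.05. The standard error of a log2 fold change is its size over the square root of F. Classes over the 3 groups combine calls of 2 comparisons. Their size is given beside the number expected from independent calls and beside 10 simulated data sets without effects, in which comparisons share libraries.

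In total 26 gene lists and 15 lists of cell type markers were fixed before the data were examined, as were the tests of the comparisons, the rule for named genes and most alternatives. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes and at one estimated from the data, and with fry. Their p values are adjusted over the 41 lists of a comparison. Counts of called members are given over all genes tested and adjusted over the list alone. Levels of a list in a library are sums of CPM over its measured members. Lists overlap: 18 of the 37 measured tubular injury markers and 23 of the 29 measured failed-repair genes are in another list. Genes named in the text follow the rule. It takes 10 genes fixed by name, then in each comparison the 6 largest and 6 smallest fold changes among called genes with at least 10 CPM in the higher group, no overlap between groups and a symbol other than that of a predicted gene. It adds up to 4 called members per list with the smallest p, or the 2 most abundant where none was called, and 5 genes per class. A gene taken by any part may be given in any comparison, and other genes are named only where the text says that they were chosen after their values were seen. Where a group had no counts of a gene, the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts it is the ratio with its counting interval.

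In a simulation with the dispersions of these libraries 200 of 15519 genes were changed. At 2-fold, 54%, 47% and 42% of the changed genes were recovered for 48 h and d14 against uninjured and d14 against 48 h, and at 4-fold 79%, 72% and 79%. Unchanged genes made up 5.67%, 5.56% and 4.72% of the calls. These rates may not hold here, with 29.1 to 45.8% of genes called and unequal spread between groups.

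The alternatives were DESeq2 size factors, upper-quartile scaling and no scaling beyond library size in place of TMM, no filter beyond 1 count and a filter of 5 CPM in 3 libraries, DESeq2 1.42.0 (Wald test), limma voom with sample quality weights, a test against a 2-fold change (glmTreat), the replicate number as a block, fits to only the groups compared, and leaving out each library in turn. Unrounded counts could not be tested. Chosen after seeing the data were thinning of every library to the smallest total, leaving out 48 h replicates 1 and 2 together, and list medians over members found in no other list. Locations and figures were made with Python 3.11.15 and matplotlib 3.10.9.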

Results

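RNA of sorted tdTomato-positive kidney cells was measured in 9 libraries: 3 of uninjured Slc34a1-labelled proximal tubule cells, 3 of Sox9-labelled cells 48 h after ischemia-reperfusion and 3 of cells labelled through Sox9 late, between days 10 and 14 after injury (d14). Total counts were 51631204, 31585507 and 46598692 in the uninjured libraries, 21023784, 8036054 and 23794029 at 48 h and 19239354, 20648604 and 30414758 at d14. Values below are TMM-scaled CPM as mean ± SD over the 3 libraries of a group, and log2 fold changes carry their SE. The study asked how cells that switch Sox9 on early differ from cells that still express it at d14, and each group was compared with the others.

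Libraries separated by group, with 52.5% of the variance of log2 CPM on the leading component and 19.0% on the next. Pearson correlations between replicates, across genes, were 0.970 to 0.980 in uninjured cells, 0.899 to 0.945 at 48 h and 0.955 to 0.964 at d14, and the biological coefficient of variation was 0.223, 0.399 and 0.249. Mitochondrial transcripts took 27.1 ± 2.08% of counts in uninjured cells, 37.0 ± 3.75% at 48 h and 21.3 ± 5.36% at d14. The 50 most abundant genes held 43.0 to 46.8%, 49.8 to 51.6% and 26.3 to 38.3% of counts. TMM factors were 0.846 to 0.902, 0.848 to 0.912 and 1.21 to 1.48, so that without TMM the median log2 fold change of all genes shifted by 0.564 in d14 against uninjured (to 0.626) and by 0.571 in d14 against 48 h (to 0.629). The transcript CT010467.1 held 5.06% of counts in 48 h replicate 3 and 3.53% in d14 replicate 2, against 0.954 to 1.51% in the others.

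The genes fixed by name lie in GRCm38 (mm10) as follows. Sox9 (ENSMUSG00000000567.5) is on chromosome 11 from 112782224 to 112787760, and Havcr1 (ENSMUSG00000040405.13) is on chromosome 11 from 46735080 to 46779578. Cdh6 (ENSMUSG00000039385.5) is on chromosome 15 from 13028701 to 13173675, and Krt8 (ENSMUSG00000049382.10) is on chromosome 15 from 101996698 to 102004482. Lcn2 (ENSMUSG00000026822.14) is on chromosome 2 from 32384633 to 32388252, as is Lrp2 (ENSMUSG00000027070.14) from 69424340 to 69586065. Slc34a1 (ENSMUSG00000021490.11) is on chromosome 13 from 55398187 to 55415592, Vcam1 (ENSMUSG00000027962.14) on chromosome 3 from 116109949 to 116129688, Wnt4 (ENSMUSG00000036856.4) on chromosome 4 from 137277489 to 137299726 and Mki67 (ENSMUSG00000031004.8) on chromosome 7 from 135689784 to 135716361. All are annotated as protein-coding.

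Cells labelled through Sox9 at 48 h held more tubular injury transcripts (31 of 37 genes higher, none lower) and fewer proximal tubule transcripts (40 of 60 lower, none higher) than uninjured cells. Of cell cycle genes 34 of 46, of neutrophil markers 7 of 8 and of macrophage markers 12 of 19 were higher and none lower. Camera called these 5 lists, but they were at adjusted p = 0.0581, 0.189, 0.438, 0.0974 and 0.317 with an estimated correlation. Havcr1, which encodes the injury marker KIM-1, rose from 0.362 ± 0.369 to 247 ± 232 CPM, and Lcn2, which encodes the siderophore-binding lipocalin NGAL, from 0.21 ± 0.113 to 241 ± 165 CPM. Lrp2, which encodes the endocytic receptor megalin, fell from 4370 ± 772 to 1600 ± 504 CPM. Of 15519 genes tested, 2700 were higher and 1818 lower at 48 h.

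Sox9, by which these cells were selected (no test of injury), rose by 5.69 ± 0.65 on the log2 scale (adjusted p = 2.88e-04), from 0.274 ± 0.318 to 14.9 ± 7.28 CPM. Cdh6, a cadherin of the developing nephron, rose by 3.65 ± 0.73 (adjusted p = 0.00745), Wnt4 by 2.62 ± 0.53 (adjusted p = 0.00406) and the simple-epithelium keratin Krt8 by 1.14 ± 0.20 (adjusted p = 0.00155). The adhesion molecule Vcam1 was at 14.9 ± 18.9 against 1.73 ± 0.635 CPM and did not pass the test (adjusted p = 0.0549). Slc34a1, by which uninjured cells were selected, was at 2480 ± 1710 CPM against a mean of 4740 CPM, also short of the threshold (adjusted p = 0.126). Besides Lcn2 and Havcr1, the largest increases were in Sprr2f, a cornified-envelope gene with no counts in uninjured cells and at least 811-fold higher at 48 h, the chitinase-like Chil3 (40.1 ± 21.5 against 0.16 ± 0.0745 CPM), the arginase Arg2 (7.95 ± 0.83) and Serpina10 (7.47 ± 1.40). The largest decreases were in the methyltransferase Inmt (-6.44 ± 0.79), Cyp2d9 (-5.37 ± 0.77), Cyp2d12 (-5.33 ± 0.79), Hpd of tyrosine breakdown (-4.78 ± 0.86) and the organic anion transporter Slc22a19 (-4.33 ± 0.81). With limma voom and sample weights Havcr1, Lcn2, Serpina10, Cyp2d9 and Slc22a19 no longer passed at 48 h, and without 48 h replicates 1 and 2 neither Cyp2d9 nor Wnt4 passed.

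Of 37 tubular injury markers 31 were higher at 48 h and none lower (34 higher adjusted over the list alone), among them S100a6 (5.69 ± 0.25) and clusterin (Clu, 6.49 ± 0.30). Of 29 genes tied to failed repair of the proximal tubule 19 were higher and none lower (22 higher adjusted over the list alone), with Spp1, which encodes osteopontin, going from 327 to 13700 CPM. Of 29 cytoskeletal and mesenchymal genes 20 were higher and none lower, the same adjusted over the list alone, including Tmsb10 (4.42 ± 0.20) and Flna (3.41 ± 0.25). Camera gave adjusted p = 2.31e-43, 3.27e-10 and 2.62e-14 for these 3 lists. These calls were lost at adjusted p = 0.0581, 0.218 and 0.103 with an estimated correlation. Fry kept them (adjusted p = 1.53e-04, 0.0025 and 4.21e-04) and most such calls in each comparison.

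Of 60 proximal tubule identity and transport genes 40 were lower and none higher (43 lower adjusted over the list alone). The organic anion transporter Slc22a8 fell by 2.52 ± 0.23 and the amino acid transporter subunit Slc7a9 by 1.52 ± 0.17. The list summed to 69900 ± 7030 CPM in uninjured cells and 26100 ± 10700 CPM at 48 h. Of 13 genes of gluconeogenesis and fructose metabolism 8 were lower and 3 higher, the same adjusted over the list alone, with Fbp1 at -1.52 ± 0.14. The 8 became 4 or 5 without any 1 uninjured library or without 48 h replicate 3. The 3 became 1 without uninjured replicate 1 or 3 or 48 h replicate 2 or 3. Of 41 fatty acid oxidation genes 7 were lower and 3 higher (7 and 2 adjusted over the list alone), among them the enoyl-CoA hydratase Echs1 (-0.77 ± 0.12). In this list the median (0.0257) and mean (0.290) were positive while camera pointed down (adjusted p = 0.191). Its summed CPM in 48 h replicate 2 was 16470, against 6816 and 6768 in the other replicates, and without that library 18 were lower. Without 48 h replicate 1 there were 9 higher, and 0 or 1 without any 1 uninjured library or 48 h replicate 2. Of 61 nuclear genes of oxidative phosphorylation 18 were lower and none higher, the same adjusted over the list alone, and 7 or 8 were lower without uninjured replicate 1 or 48 h replicate 3. Of 13 mitochondrially encoded genes mt-Co2 and mt-Atp6 (1.23 ± 0.31) were higher, the same count adjusted over the list alone. That count was 1 without uninjured replicate 1, 5 without d14 replicate 1 and 0 without 48 h replicates 1 and 2 together. Of 25 cholesterol synthesis genes 10 were lower and none higher, the same adjusted over the list alone, among them Idi1 (-2.14 ± 0.30). There were 6 lower without uninjured replicate 1 or 3, and 1 higher without 48 h replicate 2 or 3. Camera called the proximal tubule (adjusted p = 1.34e-17), gluconeogenesis (0.00900), oxidative phosphorylation (0.00339) and cholesterol lists (7.97e-04) lower, and with an estimated correlation the adjusted p was 0.189, 0.383, 0.720 and 0.317. It did not call the mitochondrially encoded list (adjusted p = 0.127).

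Of 21 glycolysis genes 12 were higher and 1 lower at 48 h (13 and 1 adjusted over the list alone), such as Hk1 (3.41 ± 0.13) and the pyruvate kinase Pkm (3.27 ± 0.18). Of 46 cell cycle genes 34 were higher and none lower (43 higher adjusted over the list alone), such as Uhrf1 (4.37 ± 0.61). The list summed to 953, 348 and 772 CPM in the 48 h replicates, the second within the 269.7 to 364.6 CPM of uninjured libraries. Its median log2 fold change was 3.25, and 2.15 without 48 h replicate 1, the library in which endothelial markers were also highest, and 19 to 22 members were called without uninjured replicate 2 or 3. The proliferation marker Mki67 was at 98.1, 2.30 and 25.9 CPM in the 48 h replicates against a mean of 3.10 CPM (log2 fold change 3.79 ± 1.06, adjusted p = 0.0313), and it failed the test when any library except 48 h replicate 2 or d14 replicate 3 was left out. Of 22 unfolded protein response genes 9 were higher and 1 lower (13 and 1 adjusted over the list alone), with the chaperone Hspa5 at 1.07 ± 0.12. Of 78 ribosomal protein genes 48 were higher and none lower (57 higher adjusted over the list alone) by a median of 0.38, for example Rpl12 (0.94 ± 0.14). That count was 21 without TMM, and 19 to 29 without any 1 uninjured library or without 48 h replicate 3. Of 28 p53 and senescence genes 13 were higher and 1 lower (15 and 1 adjusted over the list alone), among them the cell cycle inhibitors Cdkn1a (3.09 ± 0.44) and Cdkn2b (5.13 ± 0.87). The lower gene of glycolysis was not called without uninjured replicate 2 or 48 h replicate 3, nor were those of the unfolded protein and p53 lists, for which the same held without uninjured replicate 3. There were 2 unfolded protein genes lower without 48 h replicate 2 and 2 p53 genes lower without 48 h replicate 1. Camera gave adjusted p = 4.49e-08, 4.84e-07, 0.00291, 3.64e-05 and 0.00339 for glycolysis, cell cycle, unfolded protein response, ribosomal proteins and p53. With an estimated correlation these became adjusted p = 0.0974, 0.438, 0.317, 0.633 and 0.0974.

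Of 32 immediate early and dissociation stress genes 23 were higher and 1 lower (25 and 1 adjusted over the list alone), including Klf4 (3.45 ± 0.27) and the cytokine signalling inhibitor Socs3 (4.21 ± 0.35). Of 36 chemokine and NF-kB response genes 24 were higher and 1 lower (27 and 1 adjusted over the list alone), with Relb at 2.83 ± 0.37 and the neutrophil chemokine Cxcl2, with 1 count in uninjured cells, at a ratio of 358 (interval 63.2 to 14200). Of 33 interferon response genes 12 were higher and none lower (14 higher adjusted over the list alone), among them Oas2 (4.46 ± 0.70). The interferon count was 5 or 6 without uninjured replicates 1 or 3 or 48 h replicate 3, and 22 without 48 h replicate 2. The lower immediate early gene was not called when any library except 48 h replicate 1 was left out, and without that library 2 chemokine genes were lower. Of 20 antigen presentation genes 8 were higher and none lower (9 higher adjusted over the list alone), for example the immunoproteasome subunit Psmb10 (2.00 ± 0.29), with 2 to 4 higher without any 1 uninjured library or without 48 h replicate 3, and 1 lower without 48 h replicate 1 or d14 replicate 1. Camera called the early response (adjusted p = 1.28e-13), chemokine (7.06e-07) and interferon lists (0.0121). These were at adjusted p = 0.0624, 0.317 and 0.693 with an estimated correlation. It did not call antigen presentation (adjusted p = 0.201).

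Of 31 nephron development and progenitor genes 13 were higher and 3 lower at 48 h. Unless given, counts here were the same adjusted over the list alone. Sox4 rose by 3.46 ± 0.25 and the Notch ligand Jag1 by 2.44 ± 0.27, while the R-spondin receptor Lgr4 fell by 1.12 ± 0.12. Of 17 cadherins 6 were higher and 1 lower (7 and 1 adjusted over the list alone), with Cdh3 at 4.58 ± 0.31, Cdh1, which encodes E-cadherin, at 1.21 ± 0.14 and the protocadherin Pcdh1 at -1.02 ± 0.17. Of 11 measured Wnt ligand and secretion genes 4 were higher and none lower. The 4 were Wnt9b (2.70 ± 0.39), Wnt7b (4.93 ± 0.72), Wnt4 and Wnt5a (1.55 ± 0.38). The median of this list was 1.55, or 1.22 with Wnt7a, which had no counts in uninjured cells, at its bound, and 0.00609 over the 7 members found in no other list. Over these 7 it was 0.484 instead of 2.13 in d14 against uninjured, and 1.08 instead of 1.88 in d14 against 48 h. Of 17 canonical Wnt response genes 3 were higher and 1 lower. Cd44 was at 5.13 ± 0.49 and Rnf43 at 1.58 ± 0.31. The protease Mmp7 (3 counts in uninjured cells) was at a ratio of 26.1 (interval 8.18 to 133). With 48 h replicate 1 left out there were 5 higher, the lower gene was not called without uninjured replicate 1 or 3, 48 h replicate 2 or 3 or d14 replicate 2 or 3, and Mmp7 failed the test without 48 h replicate 3. Of 20 Notch pathway genes 7 were higher, such as Hes1 (1.65 ± 0.28), and none lower (1 without 48 h replicate 1 or 2). Of 21 Hippo YAP targets 10 were higher and none lower, led by Ptpn14 (2.92 ± 0.21). There were 6 higher without uninjured replicate 3 or 48 h replicate 3, and 1 lower without the latter. Of 42 extracellular matrix genes 17 were higher and 5 lower (20 and 5 adjusted over the list alone), including Thbs1 (3.20 ± 0.19) and Timp1, with 2 counts in uninjured cells, at a ratio of 288 (interval 78.9 to 2390). The 5 lower became 3 without any 1 uninjured or d14 library or without 48 h replicate 2. Of 31 profibrotic secreted factors 15 were higher and 2 lower (16 and 2 adjusted over the list alone), with the EGF receptor ligand Tgfa at 3.18 ± 0.47 and Vegfa at -1.24 ± 0.15. The 2 lower became 1 without any 1 uninjured library or 48 h replicate 1. Camera called the nephron development (adjusted p = 7.50e-04), cadherin (0.00900), Hippo (0.00399), matrix (2.15e-04) and profibrotic lists (7.49e-04) higher. They were at adjusted p = 0.0624, 0.225, 0.317, 0.218 and 0.189 with an estimated correlation. It did not call the Wnt ligand (0.0767), canonical Wnt (0.574) and Notch lists (0.0679).

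Markers of other kidney and blood cells were measured beside these groups. At 48 h 13 of 14 collecting duct principal cell markers were higher and none lower, with the water channel Aqp2 at 107 against 4.65 CPM, and the list summed to 906 ± 236 against 226 ± 24.2 CPM. Of 15 intercalated cell markers 10 were higher and none lower, such as the ammonia transporter Rhcg (2.49 ± 0.15). Both counts were the same adjusted over the list alone. Of 14 loop of Henle markers 8 were higher and 1 lower (10 and 2 adjusted over the list alone), with uromodulin (Umod) at 2.45 ± 0.25, while 2 were lower without d14 replicate 1 or 2 and none without 48 h replicate 3. Of 7 thin limb markers 4 were higher and 1 lower, the same adjusted over the list alone, with Cldn4 at 5.53 ± 0.30 and the water channel Aqp1 at -1.63 ± 0.26. Of 12 distal convoluted and connecting tubule markers 5 were higher and 3 lower, the same adjusted over the list alone, including Trpv5 (3.70 ± 0.52) and Kl, which encodes klotho (-1.72 ± 0.17). Of 8 neutrophil markers 7 were higher and none lower (8 adjusted over the list alone), among them Mmp9 (7.02 ± 0.37) and the chemokine receptor Cxcr2 (6.59 ± 0.47), and the list summed to 236 ± 114 against 9.42 ± 4.29 CPM. Of 19 macrophage and monocyte markers 12 were higher and none lower (16 higher adjusted over the list alone), such as Itgam (4.97 ± 0.41). Of 13 podocyte markers 4 (such as Synpo, Plce1 and Nes), of 9 parietal epithelium markers 4 (such as Ncam1, Akap12 and Dkk3) and of 5 urothelium markers 3 (Sprr1a, Psca and Krt15, at least 318-, 18.8- and 24.7-fold) were higher and none lower, the same adjusted over the list alone. The urothelium median of 6.77 became 4.24 with genes absent from uninjured cells at their bounds, and 5 were higher without 48 h replicate 2. Nes failed the test without uninjured replicate 1 or 2 or 48 h replicate 3. Of 12 fibroblast and pericyte markers Notch3 (1.64 ± 0.37) and Pi16 (2.11 ± 0.52) were higher and Thy1, with 1 count at 48 h, was lower at a ratio of 19.2 (interval 3.28 to 773), and adjusted over the list alone 2 were higher and none lower. Thy1 failed the test when any of the 9 libraries was left out, and Pi16 without 48 h replicate 1. The fibroblast median (0.0817) and mean (-0.025) differed in sign. No member of the endothelium (18 measured, Plvap at 87.1 against 17.4 CPM), smooth muscle (7, Smtn at 71.7 against 61.3), lymphocyte (4, Ighm at 2.55 against 1.53) or erythrocyte and platelet lists (8, Hbb-bs at 60.4 against 34.7) was called by edgeR, over all genes or adjusted over the list alone. At unadjusted p under 0.05 there were 6 endothelial markers and 0 of the others, and DESeq2 called 4 and 0. Endothelial markers summed to 1029 CPM in 48 h replicate 1 against 124 and 204 CPM in the other replicates, and 5 were called higher without 48 h replicate 2 and 1 without 48 h replicate 3. Without 48 h replicate 3 there was 1 podocyte and 1 parietal marker lower, and without d14 replicate 3 there was 1 lymphocyte marker lower. Camera called principal cells (adjusted p = 3.29e-19), intercalated cells (4.03e-09), loop of Henle (7.50e-04), thin limb (0.00377), neutrophils (2.00e-08), macrophages (5.30e-07) and urothelium (0.0481). With an estimated correlation these became adjusted p = 0.0581, 0.0624, 0.225, 0.0974, 0.0974, 0.317 and 0.218. The lists of distal tubule, podocytes, parietal epithelium, endothelium, fibroblasts, smooth muscle, lymphocytes and erythrocytes were not called (adjusted p = 0.247 to 0.877).

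**Figure D1:**
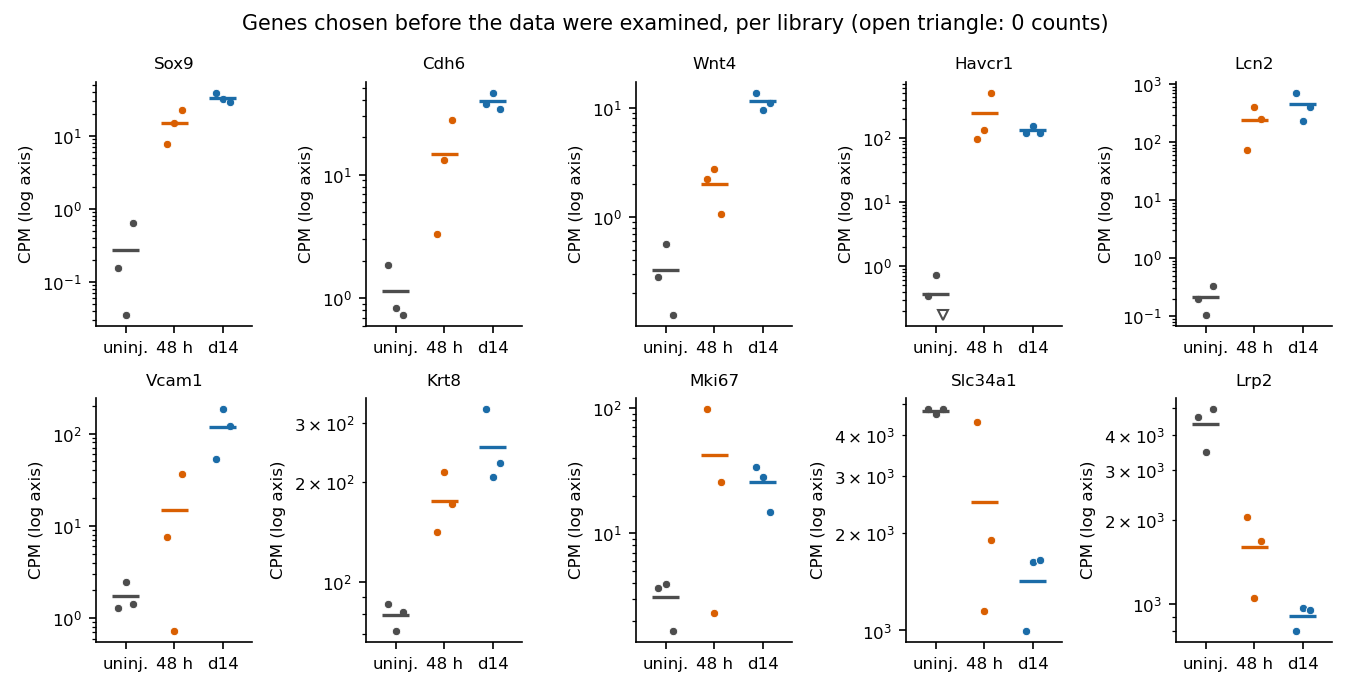
CPM (log axis, TMM-scaled) of the 10 genes fixed by name in each library, with points for the 3 libraries of a group, bars for group means and an open triangle for a library without counts. Sox9, Cdh6, Wnt4, Lcn2 and Krt8 lie above all uninjured libraries in every Sox9-labelled library, and Mki67 spreads from 2.30 to 98.1 CPM at 48 h.

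The comparison of d14 with uninjured cells asked what distinguishes cells that expressed Sox9 2 weeks after injury. More members were higher than lower among nephron development genes (21 and 4), distal convoluted and connecting tubule markers (10 and 1), injury markers (31 and none), matrix genes (26 and 5) and chemokine genes (29 and 2). More were lower among proximal tubule (54, none higher) and fatty acid oxidation genes (30, none higher). With an estimated correlation nephron development kept its camera call (adjusted p = 0.0305), and the others lost theirs at adjusted p = 0.0525, 0.119, 0.161, 0.319, 0.122 and 0.416. Sox9, selected for here too, rose by 6.84 ± 0.66 (adjusted p = 3.31e-05) to 33.2 ± 5.07 CPM, and Cdh6 by 5.06 ± 0.76 (adjusted p = 8.05e-04) to 39.0 ± 6.22 CPM. Wnt4 rose by 5.18 ± 0.55 (adjusted p = 1.86e-05), and Lrp2 fell by 2.27 ± 0.24 (adjusted p = 2.06e-05) to 906 ± 93.1 CPM. Of 15519 genes 3898 were higher and 3214 lower, and without TMM the split was 7315 and 1417.

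Vcam1 rose by 6.14 ± 1.14 (adjusted p = 0.00305) to 119 ± 65.8 CPM, Lcn2 by 10.98 ± 1.01 (adjusted p = 5.89e-05) to 448 ± 247 CPM, Havcr1 by 8.62 ± 1.05 (adjusted p = 2.92e-04) to 132 ± 19.4 CPM and Krt8 by 1.68 ± 0.20 (adjusted p = 4.31e-05) to 255 ± 66.2 CPM. Slc34a1 fell by 1.74 ± 0.43 (adjusted p = 0.00787) to 1420 ± 371 CPM. Mki67 was at 25.8 ± 9.82 CPM (3.06 ± 1.04, adjusted p = 0.0430), a call lost without any of the uninjured or d14 libraries and without 48 h replicate 3. The largest increases included 5 genes with no counts in uninjured cells: Sprr1a (at least 933-fold), the interleukin 36 gene Il1f6 (at least 649-fold), Sprr2f (at least 476-fold), Arhgap36 (at least 470-fold) and the peroxidase Lpo (at least 388-fold). The largest decreases were in Cyp2d12 (-6.74 ± 0.84), Hpd (-6.65 ± 0.92), Cyp2d9 (-6.02 ± 0.77) and the nuclease Dnase1 (-5.66 ± 0.71).

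Of 31 nephron development and progenitor genes 21 were higher and 4 lower at d14 (21 and 6 adjusted over the list alone), with Sox4 at 5.08 ± 0.26 and Jag1 at 4.29 ± 0.28. The 4 lower became 2 without uninjured replicate 1 or d14 replicate 1 or 2, and 1 without TMM. Camera called this list (adjusted p = 1.44e-07). Its median of 1.64 was 1.06 over 19 members in no other list, and 0.994 instead of 1.11 against 48 h. Of 17 cadherins 10 were higher and 1 lower, the same adjusted over the list alone, including Cdh3 (7.07 ± 0.33) and Cdh1 (2.71 ± 0.15). With 48 h replicate 1 left out there were 2 lower, and none without uninjured replicate 3, d14 replicate 3 or TMM. Of 11 Wnt ligand and secretion genes 7 were higher and none lower (7 and 1 adjusted over the list alone), with Wnt9b at 5.21 ± 0.40, Wnt7b at 7.04 ± 0.74 and Wnt7a at least 91.7-fold higher, and 1 was lower without uninjured replicate 3 or 48 h replicate 2. Of 17 canonical Wnt response genes 6 were higher and 2 lower (7 and 2 adjusted over the list alone), with Rnf43 at 3.20 ± 0.31, Cd44 at 5.71 ± 0.50, Mmp7 at a ratio of 354 (interval 121 to 1720) and Sp5 at -2.45 ± 0.35. Of 20 Notch pathway genes 9 were higher and 4 lower, the same adjusted over the list alone, such as Maml2 (3.69 ± 0.26). The 4 lower became 2 without uninjured replicate 2 or 3, d14 replicate 1 or 3, or TMM. Of 21 Hippo YAP targets 10 were higher and none lower, the same adjusted over the list alone, with Ptpn14 at 4.94 ± 0.22 and Yap1 itself at 1.05 ± 0.13, with 16 higher without TMM and 1 lower without 48 h replicate 1. Camera called cadherins (adjusted p = 4.14e-04), Wnt ligands (0.0158) and Hippo targets (0.00359). The lists were at adjusted p = 0.144, 0.244 and 0.333 with an estimated correlation. Fry, not camera (0.472 and 0.0794), called canonical Wnt (2.44e-04) and Notch (0.00111).

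Of 37 tubular injury markers 31 were higher and none lower (32 higher adjusted over the list alone), among them Clu (7.61 ± 0.32) and the keratin Krt7 (5.55 ± 0.24). Of 29 failed-repair genes 27 were higher and none lower (28 higher adjusted over the list alone), including Ncam1 (3.88 ± 0.29) and Spp1 (4.68 ± 0.39). Of 42 extracellular matrix genes 26 were higher and 5 lower (28 and 5 adjusted over the list alone), such as Thbs1 (4.75 ± 0.20) and the collagen chain Col5a2 (5.12 ± 0.32). The 5 lower became 2 without TMM, and the list's sum was 3830 ± 43.0 against 3780 ± 170 CPM. Among the profibrotic, chemokine and immediate early genes given next, the 2 lower became 1 without d14 replicate 1 or 3, without uninjured replicate 1 (the former lists) and without uninjured replicate 3 (the last). There was 1 injury marker and 1 failed-repair gene lower without 48 h replicate 1 or 2, and 1 cytoskeletal and 1 interferon gene lower without d14 replicate 2. Of 31 profibrotic secreted factors 19 were higher and 2 lower (20 and 3 adjusted over the list alone), including Tgfa (4.58 ± 0.48) and Wnt4. Of 29 cytoskeletal genes 16 were higher and none lower, the same adjusted over the list alone, with Tmsb10 at 4.63 ± 0.20. Of 36 chemokine and NF-kB genes 29 were higher and 2 lower, the same adjusted over the list alone, with Tnfaip2 at 4.28 ± 0.33. Of 33 interferon response genes 19 were higher and none lower (20 higher adjusted over the list alone), such as Irf1 (2.19 ± 0.30). Of 20 antigen presentation genes 11 were higher and 1 lower (13 and 1 adjusted over the list alone), with the peptide-loading factor Tapbp at 1.52 ± 0.17. Of 32 immediate early genes 23 were higher and 2 lower (24 and 2 adjusted over the list alone), among them Socs3 (4.79 ± 0.35). Camera called all 9 of these lists, with adjusted p = 0.0195 for interferon and 0.0154 for antigen presentation as the highest. With an estimated correlation they were at adjusted p = 0.119, 0.187, 0.161, 0.187, 0.232, 0.319, 0.704, 0.669 and 0.122, in the order given.

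Of 60 proximal tubule identity and transport genes 54 were lower and none higher (55 lower adjusted over the list alone), with the medium-chain acyl-CoA synthetase Acsm1 at -3.64 ± 0.22 and the dicarboxylate transporter Slc13a3 at -2.58 ± 0.16. The list summed to 12500 ± 2730 CPM. Of 13 gluconeogenesis and fructose genes 12 were lower and 1 higher, the same adjusted over the list alone, with Fbp1 at -2.89 ± 0.15. Of 41 fatty acid oxidation genes 30 were lower and none higher (31 lower and 1 higher adjusted over the list alone), including catalase (Cat, -2.17 ± 0.16), while 1 was higher without uninjured replicate 3, 48 h replicate 2 or 3 or d14 replicate 1. Of 61 nuclear oxidative phosphorylation genes 54 were lower and none higher (57 lower adjusted over the list alone) by a median of 0.60 on the log2 scale, such as Sdhc (-1.09 ± 0.12). Without TMM, which moved all genes by the 0.564 given above, 7 were lower, and the family's median stayed below that of all genes. Of 13 mitochondrially encoded genes 10 were lower and none higher (11 lower adjusted over the list alone), with mt-Nd3 at -1.47 ± 0.26, and 3 were lower without TMM and 6 without uninjured replicate 1 or 3. Camera called these 5 lists lower (adjusted p from 8.80e-28 to 0.00430). These were at adjusted p = 0.122, 0.122, 0.416, 0.481 and 0.562 with an estimated correlation.

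Of 21 glycolysis genes 10 were higher and 5 lower at d14, the same adjusted over the list alone, with Hk1 at 5.07 ± 0.14 and the pyruvate dehydrogenase kinase Pdk1 at 2.56 ± 0.19, and 2 were lower without TMM. Of 46 cell cycle genes 18 were higher and none lower (16 higher adjusted over the list alone), with Gins2 at 2.08 ± 0.34 and Uhrf1 at 3.58 ± 0.60. That count was 8 to 10 without any 1 uninjured library, 9 without d14 replicate 1, 31 without 48 h replicate 2 and 30 without TMM, and 1 was lower without 48 h replicate 1. Of 28 p53 and senescence genes 13 were higher and 2 lower, the same adjusted over the list alone, including Cdkn2b (7.24 ± 0.88), with 21 higher without TMM and 1 lower without uninjured replicate 1 or any 1 d14 library. Of 25 cholesterol synthesis genes 3 were higher and 10 lower, the same adjusted over the list alone, and without TMM 8 were higher and 6 lower. Of 22 unfolded protein response genes 2 were higher and 4 lower (1 and 3 adjusted over the list alone), with Asns at 3.48 ± 0.38 and Herpud1 at -1.46 ± 0.21. Without TMM 15 were higher and 2 lower, and 1 was higher without uninjured replicate 1 or 2, 48 h replicate 3 or d14 replicate 3. In the unfolded protein list the median (0.0601) and mean (0.288) were positive while camera pointed down (adjusted p = 0.642). Of 78 ribosomal protein genes 1 was higher and 10 lower (none higher and 5 lower adjusted over the list alone), such as Rps25 (-0.54 ± 0.10) and Rpl10 (-0.51 ± 0.11), while without TMM 56 were higher and none lower. The 10 were 5 or 6 without uninjured replicate 1 or d14 replicate 2 or 3, and none was higher without any 1 uninjured library or d14 replicate 1 or 3. Camera called glycolysis (adjusted p = 7.56e-04) and cell cycle (0.0356). They were at adjusted p = 0.223 and 0.790 with an estimated correlation. No call was made for the p53 (0.0794), cholesterol (0.0603) or ribosomal lists (0.0959).

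Segment markers stood apart from the proximal tubule genes. Of 14 loop of Henle markers 11 were higher and 1 lower at d14 (12 and 1 adjusted over the list alone), with Umod going from 129 to 3420 CPM, the potassium channel Kcnj1 from 10.2 to 423 CPM and the list from 518 ± 57.2 to 5280 ± 1570 CPM. Of 12 distal convoluted and connecting tubule markers 10 were higher and 1 lower, the same adjusted over the list alone, with the thiazide-sensitive cotransporter Slc12a3 from 57.5 to 2770 CPM and Calb1 at 2.57 ± 0.15, and the list from 1440 ± 58.6 to 5470 ± 988 CPM. Of 14 principal cell markers 13 were higher and none lower, with the sodium channel subunit Scnn1a (4.89 ± 0.17), and of 15 intercalated cell markers 14 were higher and none lower, with Rhcg at 4.30 ± 0.16, all the same adjusted over the list alone. Their sums were 1590 ± 246 and 472 ± 43.9 CPM, against 226 ± 24.2 and 41.5 ± 8.80 CPM. Of 7 thin limb markers 5 were higher and 1 lower, the same adjusted over the list alone, with Cldn4 at 6.69 ± 0.31 and Aqp1 at -2.10 ± 0.27, and the list summed to 312 ± 17.7 against 612 ± 83.3 CPM. Camera called these 5 lists (adjusted p from 2.74e-14 to 0.0281). The lists were at adjusted p = 0.122, 0.0525, 0.0664, 0.0631 and 0.166 with an estimated correlation.

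Of 19 macrophage markers 7 were higher and none lower at d14, the same adjusted over the list alone, among them Cd14 (4.46 ± 0.45). The count was 4 without uninjured replicate 1 or 3 or d14 replicate 2 and 13 without TMM. Of 8 neutrophil markers Mmp9 alone was higher (2.22 ± 0.37) and none lower, the same adjusted over the list alone, and the list's median (0.062) was positive while camera pointed down (adjusted p = 0.944). Of 13 podocyte markers 5 were higher and 2 lower, the same adjusted over the list alone, including Plce1 (3.68 ± 0.43), with a median of -0.299 and a mean of 0.287. The 2 lower became 0 or 1 without any 1 uninjured library or d14 replicate 1 or 3. Of 9 parietal epithelium markers 4 were higher and 1 lower, and of 5 urothelium markers 3 were higher and none lower (Sprr1a, with Psca at least 38.9-fold and Krt15 at least 17.4-fold), the same adjusted over the list alone. The lower parietal marker was not called without any 1 uninjured or d14 library, and 2 were lower without 48 h replicate 2. The urothelium median of 6.69 was 4.12 with these genes at their bounds. Of 12 fibroblast and pericyte markers 4 were higher and 1 lower, the same adjusted over the list alone, with Notch3 at 3.42 ± 0.38, the collagen chain Col1a1 at 3.08 against 0.156 CPM and Pi16 at -1.67 ± 0.54. The 4 became 2 without uninjured replicate 1 or 2 or d14 replicate 2 or 3, and Pi16 failed the test without uninjured replicate 2 or 3 or d14 replicate 2 or 3. Ren1, which encodes renin, (-4.28 ± 1.05) and Mylk (-0.67 ± 0.18) were lower among 7 smooth muscle markers, and Slc4a1 (1.62 ± 0.42) was higher and Itga2b (-1.60 ± 0.51) lower among 8 erythrocyte and platelet markers, with the same counts adjusted over the list alone. Mylk failed the test without d14 replicate 1, and Itga2b without uninjured replicate 1 or 3 or d14 replicate 1 or 2. No marker was called by edgeR among 18 of endothelium (Kdr at 7.28 against 24.7 CPM), of which 10 were lower without 48 h replicate 1 and 1 without d14 replicate 2, or among 4 of lymphocytes (Gzma at 1.17 against 1.27 CPM), the same adjusted over the list alone. At unadjusted p under 0.05 there were 1 and 0, and DESeq2 called 2 and 0. Without 48 h replicate 2 there were 2 endothelial markers lower, and without 48 h replicate 1 there were 2 neutrophil markers lower and without uninjured replicate 3 there was 1. Camera called none of these 10 lists (adjusted p = 0.0784 to 0.944).

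**Figure D2:**
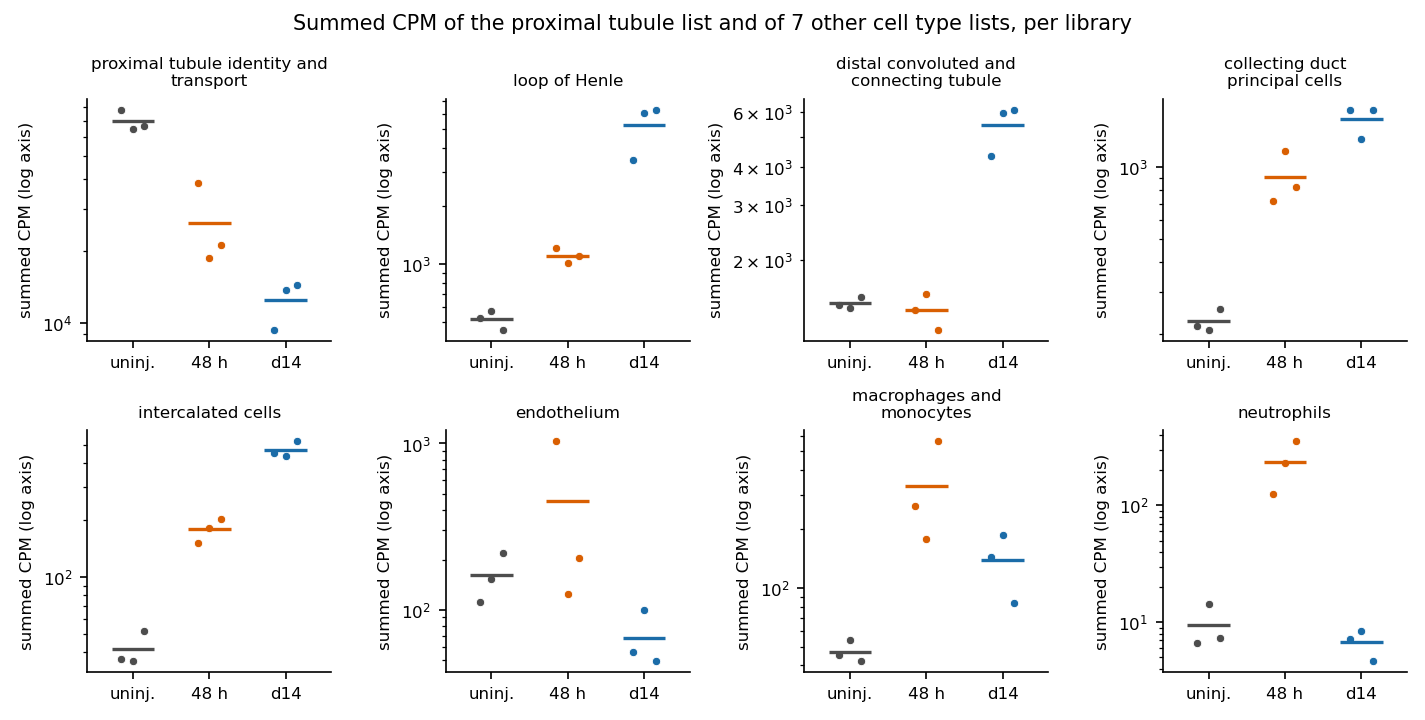
Summed CPM (log axis, TMM-scaled) of the proximal tubule list and of 7 marker lists of other cell types in each library, with points for the 3 libraries of a group and bars for group means. Proximal tubule transcripts fall from a mean of 69900 CPM to 26100 at 48 h and 12500 at d14, and neutrophil markers stand at 236 CPM at 48 h against 9.42 in uninjured cells and 6.73 at d14.

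Cells at d14 and 48 h, both labelled through Sox9, were compared next. At d14 11 of 12 distal tubule markers and 17 of 31 nephron development genes were higher (1 and 2 lower). Camera kept both calls with an estimated correlation (adjusted p = 0.0251 for each). The nephron list holds the distal nephron factor Pou3f3, so these rises were not told apart. All 8 neutrophil markers, 34 of 41 fatty acid oxidation, all 13 mitochondrially encoded and 37 of 60 proximal tubule genes were lower. These 4 camera calls were lost with an estimated correlation (adjusted p = 0.119, 0.419, 0.327 and 0.307). Wnt4 rose by 2.56 ± 0.49 (adjusted p = 0.00266), from 2.01 ± 0.859 to 11.5 ± 2.15 CPM. The neutrophil alarmins S100a8 (59.0 ± 37.0 to 0.699 ± 0.792 CPM) and S100a9 (65.2 ± 43.6 to 0.743 ± 0.34 CPM) fell as well. Of 15519 genes 2604 were higher and 2533 lower, and without TMM the split was 6812 and 934.

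Sox9 did not pass the test between the time points (1.15 ± 0.48, adjusted p = 0.0996), nor did Cdh6 (1.40 ± 0.64, 0.129), Vcam1 (2.91 ± 0.95, 0.0513), Havcr1 (-0.90 ± 0.69, 0.359), Lcn2 (0.90 ± 0.62, 0.308), Krt8 (0.54 ± 0.20, 0.0539), Slc34a1 (-0.80 ± 0.42, 0.170) or Mki67 (-0.74 ± 0.94, 0.587). Lrp2 fell by 0.82 ± 0.23 (adjusted p = 0.0212), a call lost without TMM, without 48 h replicate 1 or 3 or without any 1 d14 library. The largest increases were in the calcium buffer Pvalb of the distal convoluted tubule (7.04 ± 1.65, at 20.3 ± 22.1 CPM at d14), Arhgap36 (6.61 ± 0.87), the branched-chain aminotransferase Bcat1 (6.11 ± 0.69), Megf6 (5.30 ± 0.90) and Abca13 (4.84 ± 0.45). Pvalb failed the test without 48 h replicate 3 and with limma voom, as S100a8 did with the latter. The largest decreases, besides S100a8 and S100a9, were in Chil3 (-6.88 ± 0.90), Cxcr2 (-6.48 ± 0.47), Slfn4 (-6.37 ± 0.79) and the glutathione transferase Gsta1 (-5.54 ± 0.41).

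Of 31 nephron development genes 17 were higher and 2 lower at d14 than at 48 h (20 and 2 adjusted over the list alone). Pou3f3 was at 2.17 ± 0.20, the renal transcription factor Pax2 at 1.12 ± 0.12 and Jag1 at 1.85 ± 0.25. The 2 lower became 1 without 48 h replicate 2, d14 replicate 1 or 2, or TMM. Of 12 distal convoluted and connecting tubule markers 11 were higher and 1 lower, the same adjusted over the list alone, among them Calb1 (2.70 ± 0.15) and the kinase Wnk1 (2.01 ± 0.22). Camera called both lists (adjusted p = 3.09e-07 and 2.63e-10). Of 14 loop of Henle markers 9 were higher and 1 lower, the same adjusted over the list alone, with Kcnj1 at 2.67 ± 0.15. Of 14 principal cell markers 7 were higher and none lower (7 and 1 adjusted over the list alone), with Scnn1a at 2.10 ± 0.15, and of 15 intercalated cell markers 7 were higher and none lower (9 higher adjusted over the list alone), with Atp6v1b1 at 1.87 ± 0.16. Without TMM 12 intercalated markers were higher, without 48 h replicates 1 and 2 there were 4 principal cell markers higher, and without 48 h replicate 3 there was 1 lower. Of 7 thin limb markers Cldn4 was higher (1.16 ± 0.24) and none lower, the same adjusted over the list alone. Camera called loop (adjusted p = 3.76e-07), principal (6.60e-04) and intercalated markers (4.45e-05). These were at adjusted p = 0.179, 0.386 and 0.245 with an estimated correlation. It did not call the thin limb (0.612).

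Of 11 Wnt ligand and secretion genes 5 were higher and none lower, the same adjusted over the list alone: Wnt4, Wnt9b (2.52 ± 0.35), Wnt7a (4.87 ± 1.18), the Wnt carrier Wls (0.48 ± 0.13) and Wnt7b (2.11 ± 0.56), with 2 higher without d14 replicate 1 (Wnt7a and Wls among those lost), 8 without TMM and 1 lower without 48 h replicate 2. Wls also failed the test without d14 replicate 3. Of 17 canonical Wnt response genes 3 were higher and 3 lower, the same adjusted over the list alone, with Rnf43 at 1.62 ± 0.30, Znrf3 at 0.97 ± 0.20 and Sp5 at -1.79 ± 0.35, and 8 were higher without TMM. Of 17 cadherins 7 were higher and 3 lower (10 and 3 adjusted over the list alone), with the desmoglein Dsg2 at 2.97 ± 0.27 and Cdh1 at 1.51 ± 0.15. There were 11 higher without TMM, and 1 lower without 48 h replicate 1 or d14 replicate 1 or 3. Of 42 extracellular matrix genes 16 were higher and 2 lower (19 and 3 adjusted over the list alone), with Lamb1 at 1.67 ± 0.13 and Mmp14 at 2.34 ± 0.25, with 10 higher without d14 replicate 1 and 4 lower without 48 h replicate 2 or 3. Of 31 profibrotic factors 8 were higher and 2 lower, the same adjusted over the list alone, such as Tgfb2 (2.52 ± 0.52), with 4 higher without d14 replicate 1 and 16 without TMM. The 2 lower became 4 without 48 h replicate 1 and 0 or 1 without any of the libraries except that and uninjured replicate 1. Of 20 Notch genes 8 were higher and 4 lower (8 and 6 adjusted over the list alone), including Heyl (3.85 ± 0.70) and Rfng (-0.82 ± 0.16), with 4 or 5 higher without d14 replicate 1 or 2 or 48 h replicate 2, and 2 lower without d14 replicate 1 or 3 or TMM. Of 21 Hippo targets 6 were higher and 2 lower, the same adjusted over the list alone, with Axl at 1.81 ± 0.27. There were 10 higher without TMM, and 0 or 1 lower without 48 h replicate 3 or any 1 d14 library. Camera called Wnt ligands (adjusted p = 0.0237), cadherins (0.00111) and matrix (0.00111) higher. They were at adjusted p = 0.386, 0.215 and 0.386 with an estimated correlation. Camera did not call the canonical Wnt, profibrotic, Notch and Hippo lists (adjusted p = 0.112 to 0.612).

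Of 37 injury markers 10 were higher and 3 lower (12 and 3 adjusted over the list alone), with Krt7 at 1.81 ± 0.20 and the heme oxygenase Hmox1 at -1.75 ± 0.25. Of 29 failed-repair genes 13 were higher and 2 lower (16 and 2 adjusted over the list alone), with Dcdc2a at 3.37 ± 0.38. Without 48 h replicates 1 and 2 these lists had 3 and 5 genes higher, without TMM 18 and 20, and the failed-repair list had 20 without 48 h replicate 3. Of 36 chemokine and NF-kB genes 11 were higher and 3 lower (12 and 3 adjusted over the list alone), such as Tnfaip2 (2.01 ± 0.30). Their higher count was 6 or 7 without 48 h replicate 1 or 2 or d14 replicate 2 or 3, and 17 without 48 h replicate 3 or without TMM. Of 33 interferon genes 3 (Gbp2, Tap1 and Irf9) were higher and none lower (1 adjusted over the list alone), with 6 higher without 48 h replicate 3, 1 without d14 replicate 2 or 3 and 9 without TMM, and 3 lower without 48 h replicate 2. Irf9 failed the test without uninjured replicate 3, 48 h replicate 2 or any 1 d14 library, and Tap1 without 48 h replicate 1 or d14 replicate 2 or 3. Of 20 antigen presentation genes 6 were higher and none lower (8 adjusted over the list alone), with H2-Eb1 (2.19 ± 0.54, not called without 48 h replicate 2) and Tapbp at 0.84 ± 0.17, with 3 higher without 48 h replicate 1 or d14 replicate 2 or 3, 11 without TMM and 0 without 48 h replicates 1 and 2. Of 29 cytoskeletal genes 4 were higher and 4 lower (3 and 4 adjusted over the list alone), with S100a4 at -3.52 ± 0.78. There were 9 higher and 1 lower without TMM, 2 lower without 48 h replicate 3 and 1 lower without d14 replicate 3. Camera called the failed-repair (adjusted p = 7.07e-04), chemokine (0.0353) and antigen presentation lists (0.0281) higher. The lists were at adjusted p = 0.518, 0.725 and 0.725 with an estimated correlation. No call was made for the injury, interferon and cytoskeletal lists (adjusted p = 0.320 to 0.993).

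Of 60 proximal tubule genes 37 were lower and 2 higher (38 and 2 adjusted over the list alone), with Slc13a3 at -2.74 ± 0.16 and Acsm1 at -3.25 ± 0.21. The 2 higher became 1 without uninjured replicate 2, 48 h replicate 2 or d14 replicate 1 or 3. Of 41 fatty acid oxidation genes 34 were lower and 1 higher (35 and 1 adjusted over the list alone), with Cat at -1.52 ± 0.15. Of 13 gluconeogenesis and fructose genes 12 were lower and none higher, the same adjusted over the list alone, with Khk at -1.70 ± 0.18. All 13 mitochondrially encoded genes were lower, the same adjusted over the list alone, with mt-Nd3 at -2.03 ± 0.26, and 7 were lower without 48 h replicates 1 and 2. Of 61 nuclear oxidative phosphorylation genes 34 were lower and none higher (41 lower adjusted over the list alone), such as Ndufs6 (-0.80 ± 0.11), with 22 lower without d14 replicate 1, 15 without 48 h replicates 1 and 2, and 2 lower and 13 higher without TMM. Of 78 ribosomal protein genes 66 were lower and none higher (72 lower adjusted over the list alone), such as Rpl38 (-0.79 ± 0.11), with 35 lower without d14 replicate 2 and none without TMM, where the list's median was 0.105 and that of all genes 0.629. Of 22 unfolded protein response genes 12 were lower and 1 higher (13 and 1 adjusted over the list alone), with Manf at -1.33 ± 0.10 and Hspa5 at -1.20 ± 0.12. The higher gene was not called without 48 h replicate 3 or d14 replicate 1 or 3, and 4 were lower and 6 higher without TMM. Camera called these 7 lists lower (adjusted p from 3.73e-16 to 7.65e-05). These were at adjusted p = 0.307, 0.419, 0.144, 0.327, 0.659, 0.518 and 0.327 with an estimated correlation.

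Of 46 cell cycle genes 8 were lower and none higher (4 lower adjusted over the list alone), such as Tyms (-1.13 ± 0.24). The count was 3 without 48 h replicate 1 or d14 replicate 3, 4 or 5 without uninjured replicate 1, 48 h replicate 3 or d14 replicate 1 or 2, 21 without 48 h replicate 2 and 0 without TMM, and camera's call (adjusted p = 0.0156) was lost at adjusted p = 0.733 with an estimated correlation. Of 21 glycolysis genes 7 were higher and 8 lower, the same adjusted over the list alone, with Hk1 at 1.66 ± 0.12 and the lactate dehydrogenase Ldha at -1.23 ± 0.11, and 11 and 5 without TMM. Of 32 immediate early genes 3 were higher and 7 lower, the same adjusted over the list alone, such as Dusp1 (-1.17 ± 0.32), of 28 p53 genes 4 were higher and 5 lower, the same adjusted over the list alone, with Bbc3 at 1.77 ± 0.40 and Plk3 at -2.23 ± 0.50, and of 25 cholesterol genes 5 were higher and 5 lower, the same adjusted over the list alone, with Fdps at 1.09 ± 0.17 and Acat2 at -1.72 ± 0.20. Without TMM the immediate early, p53 and cholesterol lists had 13, 11 and 17 genes higher and 0, 2 and 2 lower. The immediate early genes had 2 to 4 lower without 48 h replicate 1 or any 1 d14 library, the p53 genes 2 or 3 lower without 48 h replicate 1 or d14 replicate 2 or 3, and the cholesterol genes 8 higher without 48 h replicate 1. The 3 higher immediate early genes became 0 or 1 without uninjured replicate 2, 48 h replicate 1 or any 1 d14 library and 6 without 48 h replicate 3, and the 4 higher p53 genes 1 or 2 without 48 h replicate 3 or d14 replicate 1 or 3. Median and mean differed in sign for glycolysis (0.0324 and -0.0652) and p53 (0.016 and -0.0372), and camera called none of these 4 lists (adjusted p = 0.687 to 0.939).

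All 8 neutrophil markers were lower at d14 than at 48 h, the same adjusted over the list alone, with Mmp9 at 1.45 against 40.6 CPM and Csf3r at -4.43 ± 0.55. Of 19 macrophage markers 7 were lower and none higher, the same adjusted over the list alone, including Itgam (-3.41 ± 0.37), with 4 lower without d14 replicate 1 or without TMM, and 1 higher without 48 h replicate 3. Of 18 endothelial markers 13 were lower and none higher (15 lower adjusted over the list alone), with Plvap at 7.23 against 87.1 CPM, a call lost without d14 replicate 1 or 3. The endothelial count was 8 without TMM or without uninjured replicate 1 or 3, 6 without 48 h replicate 1, and 1 to 5 without any 1 d14 library. Camera called these 3 lists lower (adjusted p = 4.97e-10, 0.00703 and 5.79e-04). They were at adjusted p = 0.119, 0.725 and 0.725 with an estimated correlation. Of 12 fibroblast and pericyte markers 3 were higher and 1 lower (4 and 1 adjusted over the list alone), with Notch3 at 1.78 ± 0.36 and Col1a1 at 3.70 ± 1.09. Of 13 podocyte markers 2 (Plce1 and Thsd7a) were higher and Podxl lower, of 9 parietal markers Ncam1 was higher, of 7 smooth muscle markers Mylk was lower (-0.84 ± 0.19) and of 8 erythrocyte and platelet markers Hbb-bt was lower (-2.25 ± 0.65), the same counts adjusted over the list alone. No marker of urothelium (5 measured, Sprr1a at 24.6 against 8.36 CPM) or lymphocytes (4 measured, Ighm at 1.82 against 2.55 CPM) was called by edgeR, the same adjusted over the list alone, with 0 at unadjusted p under 0.05 and 0 called by DESeq2. Podxl and Thsd7a failed the test without d14 replicate 1 or 3, Thsd7a also without 48 h replicate 3 or d14 replicate 2, Col1a1 without d14 replicate 1 or 2, and Hbb-bt without 48 h replicate 1 or 2 or d14 replicate 3. Without 48 h replicate 3 there were 4 parietal markers higher, and without d14 replicate 2 there were 4 erythrocyte and platelet markers lower and 1 fibroblast marker higher. With 48 h replicate 3 left out there was 1 urothelium marker higher, without d14 replicate 3 there was 1 lymphocyte marker higher, and without d14 replicate 1 there was 1 erythrocyte and platelet marker higher. The smooth muscle median (0.354) was positive and its mean (-0.205) negative, and the lymphocyte median (-0.0565) was negative and its mean (0.283) positive. Camera called none of these 7 lists (adjusted p = 0.133 to 0.939).

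**Figure D3:**
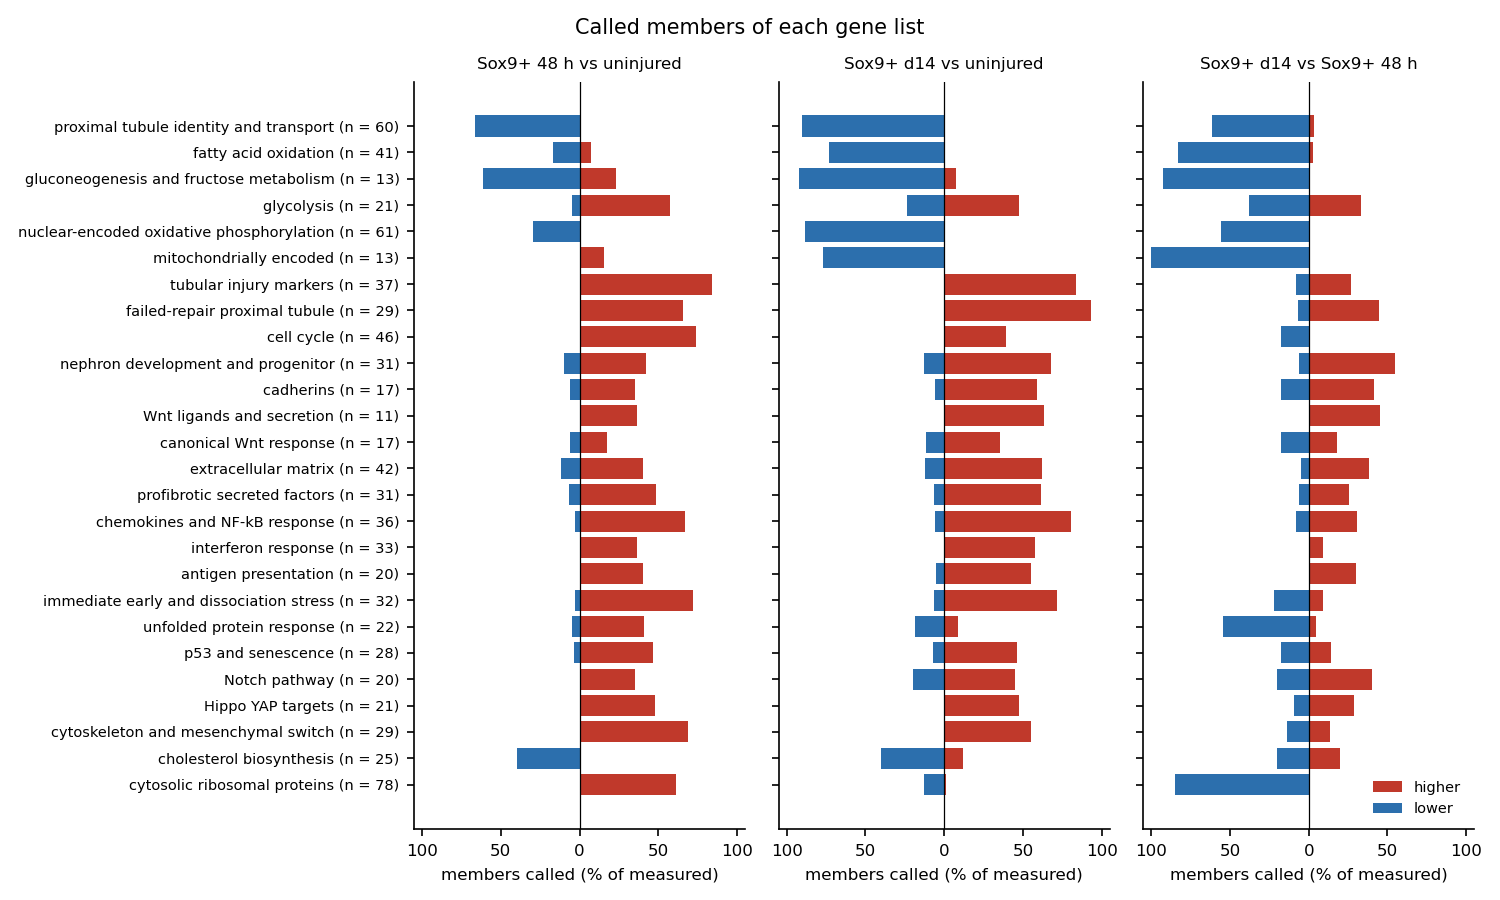
Percent of measured members of the 26 gene lists called higher (right of 0) or lower (left of 0) in each comparison by edgeR at adjusted p under 0.05, with the number measured in brackets. The proximal tubule list has 40, 54 and 37 of 60 genes lower, and the ribosomal list, 48 of 78 higher at 48 h, has 66 lower in d14 against 48 h, a direction that flips to a median of 0.105 without TMM, where that of all genes was 0.629.

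Across the 3 groups, 1993 genes were higher and 1300 lower at both times than in uninjured cells, where 678.2 and 376.5 would be expected from independent calls. Sprr2f, Lcn2, Havcr1, Serpina10 and Samd5 led the shared increases, Samd5 at 0.112 ± 0.114, 11.7 ± 5.49 and 53.3 ± 16.1 CPM in uninjured, 48 h and d14 cells, and Cyp2d9, Cyp2d12, Hpd, Inmt and Slc22a7 led the shared decreases. Another 1948 genes were higher at d14 than in both other groups (654.1 expected), such as Arhgap36, Megf6, Abca13 (11.9 ± 0.278, 14.6 ± 8.26 and 427 ± 164 CPM), Htr3a and the neuronal leucine-rich repeat gene Lrrn1. In turn 1779 genes were lower at d14 than in both (524.6 expected), such as Cyp2a5, Acsm1 (193 ± 27.7, 148 ± 36.2 and 15.5 ± 3.05 CPM), Ces2c, the steroid dehydrogenase Hsd3b3 and Cyp4a12a. There were 497 genes higher at 48 h than in uninjured cells and lower at d14 than at 48 h (440.7 expected), led by Chil3 (0.16 ± 0.0745, 40.1 ± 21.5 and 0.339 ± 0.474 CPM), Cxcr2, Slfn4, Gsta1 and S100a8. The opposite course was found in 308 genes (305.1 expected), led by Inmt, the desaturase Scd1, Bdh1 of ketone metabolism, the clock factor Npas2 and Fpgs of folate metabolism (54.6 ± 3.13, 21.8 ± 2.14 and 54.1 ± 13.8 CPM).

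In 10 simulated data sets without effects the 6 classes held 0 to 1 gene each, near-empty by construction. The 497 and 308 genes lay near expectation. Log2 fold changes of 48 h and d14 against uninjured correlated at 0.75 across genes (Spearman 0.66), against 0.473 in simulated data that share the uninjured libraries, and their covariance was 2.23 against 0.135. Genes are not independent, and 3 uninjured libraries could not be split between comparisons, so part of each overlap may rest on shared libraries.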

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

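Of the tests in this part, those on dilution and scaling of the proximal tubule list, on depth and on the cell cycle were chosen after the result was seen, and the splits of the libraries and the general leukocyte genes before. Earlier tests of depth, by thinning (void, since it leaves expected CPM unchanged) and against d14 libraries with fewer counts, were replaced after their results were seen. In 54 genes the change against uninjured cells was upward at 48 h and downward at d14, and in 30 it was the reverse, with the difference between the time points tested directly. Without TMM, which shifts all genes, 21 of the 54 turned upward at d14 and 10 kept both calls, while the 30 kept their direction at d14 and 22 of them both calls. Among genes of the naming rule, d14 minus 48 h was -1.14 for the glycolytic mutase Pgam1, -3.78 for Pi16, 1.46 for the ion channel Trpm7, 6.11 for Bcat1 and -0.763 for Rps2. Pgam1, Pi16 and Rps2 were higher at 48 h and lower at d14 than in uninjured cells, although without TMM the d14 value turns to 0.00677 for Pgam1 and 0.212 for Rps2, whose difference (-0.18) is then not called, nor is the d14 value of Pi16 (-1.07). Trpm7 and Bcat1 went the reverse way.

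The real grouping called 4518, 7112 and 5137 genes in the 3 comparisons with edgeR, and 1 of the 10 splits of the 6 libraries, the real split, gave as many in each. The highest of the other splits called 0 genes, with 1046, 150 and 872 at unadjusted p under 0.05. Splits of 3 against 3 are too few for a share under 0.05.

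Proximal tubule genes were lower at d14 than in uninjured cells. Their chi-square per degree of freedom around the weighted mean was 7.23 (6.96 without the lowest member, Hpd). Fewer proximal tubule cells need not lower members alike, so this test cannot decide. An earlier form, the SD of the log2 fold changes (0.961) against the median SE (0.268), was replaced after its result was seen. Scaling as the whole cause is argued against by a median of -1.76 without TMM. Fewer such cells, the different Cre allele and a lasting change in the cells stay open, the last untested, and other segments' markers rose beside the list.

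Transcripts of leukocytes were higher at 48 h. All 7 of 7 general leukocyte genes outside the fixed lists were called higher, among them Coro1a (28.7 against 2.90 CPM), Lcp1 (68.0 against 14.8) and Rac2 (13.8 against 1.23), as leukocytes or their RNA in the 48 h sorts would give, although a sort for tdTomato should remove unlabelled cells. Of the 7, Lcp1 alone exceeded 10 CPM in uninjured cells, and 6 were lower at d14 than at 48 h. Lower depth of the 48 h libraries, which leaves expected CPM unchanged and adds counting error, is argued against. The lowest 48 h library exceeded the highest uninjured library at least 7.82-fold in neutrophil and 3.05-fold in macrophage markers (lower ends of 95% counting intervals). Expression of these genes by injured tubule cells was not tested.

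Cell cycle genes were higher at 48 h, where replicate 1 held the most endothelial transcripts. Endothelial cells in 48 h replicate 1 as the whole cause are argued against by a median log2 fold change of 2.15 without that library. Other cell types and cycling tubule cells stay open and were not tested.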

How the results depend on the processing

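Thinning, removal of 48 h replicates 1 and 2 together and list members in no other list were chosen after the data were seen. Upper-quartile scaling, no filter beyond 1 count, the 2-fold test and fits to only the groups compared were run for counts of called genes (upper-quartile scaling also for the families below and genes of opposite course), not for other named genes or lists, nor were the 5 CPM filter and limma voom for lists. Over the others the named genes gave 7477 values with the same direction and side of the threshold, 214 that no longer passed and 4 reversed. Of list medians 1922 moved by no more than the scaled median absolute deviation of log2 fold changes over the list's genes, 44 moved further and 2 reversed. That limit is a spread between genes, not between replicates. Of counts of called list members 1661 stayed within 1.5 times and 184 did not. Of counts of called genes 212 stayed within 1.5 times and 34 did not. Without TMM the counts higher and lower were 7315 and 1417 for d14 against uninjured and 6812 and 934 for d14 against 48 h. In that setting 795 genes were lower at both times, 250 higher at 48 h and then lower, 744 lower at 48 h and then higher, 5378 higher at d14 than in both groups and 542 lower. The reversed values were also without TMM: 0.0266 for Rps25, Sox9 d14 vs uninjured, 0.0691 for Rpl10, Sox9 d14 vs uninjured, 0.0350 for Rpl28, Sox9 d14 vs uninjured, 0.0599 for Fau, Sox9 d14 vs uninjured, and the medians of oxidative phosphorylation (0.14) and ribosomal proteins (0.105) for d14 against 48 h. They moved with the shift of all genes that this setting makes. Tested against a 2-fold change, 1181 genes were higher and 128 lower at 48 h, 1970 and 865 at d14, and 333 and 321 in d14 against 48 h, as a stricter test gives by construction. The classes then held 941 genes higher and 1.0e+02 (to 2 digits) lower at both times, 89 higher at 48 h and then lower, 3 lower and then higher, and 318 higher and 187 lower at d14 than in both groups. Without 48 h replicates 1 and 2, with the lone library left assumed to vary like the other groups, 1426 genes were higher in d14 against 48 h and 1121 higher at d14 than in both groups. Leaving out each library gave 1147 to 1995 genes lower at 48 h, 841 to 1451 lower at both times, 317 to 580 higher at 48 h and then lower, and 176 to 365 lower and then higher, with fewer samples in each fit. The cause of other movements was not tested. The unrounded-count alternative was not run, since the counts are whole. Depth limits genes under the floors given above.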

Other observations

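The test of androgen-dependent genes and the 14 gene families in this part were chosen after the data were seen, and look-alike symbols were later taken out and leukocyte integrins added. Families were tested with Fisher's exact test across genes, 84 tests adjusted together, and genes are not independent replicates. At 48 h 8 of 10 measured keratins (adjusted p = 2.25e-04), 11 of 11 S100 calcium-binding proteins (1.63e-07), 7 of 10 annexins (0.00217), 8 of 13 tubulins (0.00217), 14 of 25 integrins (2.05e-04) and 9 of 18 claudins (0.0054) were higher. Among these were the leukocyte genes S100a8, S100a9, Itgam and Itgb2. At d14 8 keratins (0.00217), 7 S100 proteins (0.0233), 8 annexins (0.00217) and 9 tubulins (0.0039) were higher than in uninjured cells, while 9 claudins (adjusted p = 0.0626) and 10 integrins (0.199) did not pass. Between d14 and 48 h 5 S100 proteins and 8 integrins were lower at d14, and 4 and 7 higher.

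Of 289 solute carriers 75 were lower (adjusted p = 1.28e-10) and 59 higher at 48 h, and 125 lower (4.38e-17) and 67 higher at d14, where the median of -0.454 flips to 0.117 without TMM (88 lower, 109 higher). That setting moves the median of all genes from 0.0601 to 0.626, and the family lay below it in both settings. Of 78 mitochondrial ribosomal proteins 55 were lower and 1 higher (1.43e-19), and of 42 proteasome subunits 22 and 5 (3.34e-05), at d14 than in uninjured cells. Their medians of -0.514 and -0.309 flip to 0.0532 (5 lower, 11 higher) and 0.258 (none lower, 11 higher) without TMM through the same shift, below the median of all genes in both settings.

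Among genes chosen after their values were seen, Pck1 of gluconeogenesis was higher at 48 h (1.84) and lower at d14 (-2.61), as was the ferritin chain Fth1 (1.29 and -1.41), and the immunoglobulin receptor Pigr was lower at 48 h (-1.22) and higher at d14 (1.45). A hypothesis was that androgen-dependent kidney genes may have fallen more at d14 than female-biased ones. The difference of their medians, over 10 and 7 measured genes, was -0.987, and an exact one-sided permutation test over genes gave p = 0.185, so the question stays open.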
